A study of Arabidopsis thaliana with 30 samples.

How the data were processed

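RNA was profiled in 30 libraries from detached Arabidopsis leaves: 2 at detachment (T0), and 2 at each of 7 times on medium without (mock) and with NPA. The authors deposited TPM values in 2 tables, 1 for mock and 1 for NPA, and the T0 columns were identical in both and counted once. Per the submitters' processing notes, reads were handled with Trim Galore 0.5.0, STAR 2.7.2b and RSEM 1.3.2 on genome build TAIR10, with no order, parameters or library strandedness given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol and sequenced on an Illumina instrument. Each deposited TPM column summed to 1e6 over all genes, organelle genes included, and no scaling between libraries was seen. TPM is a share of the transcripts of its own library, so a rise of abundant genes lowers all others, and the values hold no count or depth: the depth is unknown, and no counting interval can be given.

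Of 37686 genes, 37390 matched a locus of the reference annotation (TAIR10.1) by AGI identifier and 10870 had a symbol. Coordinates are those of that annotation and were printed for the genes listed in advance and a few others. Groups came from the sample titles. Replicates were compared before they were averaged, and none of the 435 pairs of libraries held identical values. Genes with a TPM of at least 1 in at least 2 libraries were kept, which left 20654. Values were taken as log2(TPM + 1) without further scaling. All 30 libraries were fitted in 1 model with a mean per group using limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, with 15 residual degrees of freedom and a prior of 2.33, so that groups of 2 share an estimate of the spread. The comparisons were mock against T0 and NPA against mock at each of 7 times, the 6 successive steps of mock, the mean of the 7 NPA differences, and a moderated F test of whether those differences vary between times. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. The replicate numbers were not used to pair libraries, because within-group deviations of mock and NPA at the same time correlated across genes (which are not independent replicates) with r of -0.57, -0.58, -0.36, 0.33, 0.05, -0.14 and -0.14 from 6 h to 5 d.

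Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The 15 pathway lists were wound and jasmonate, auxin synthesis, auxin response, auxin transport, root founder and primordium, cell cycle, photosynthesis, senescence, ribosome, cytokinin, ethylene, abscisic acid, salicylate and defence, hypoxia and circadian clock. The 9 marker lists were xylem, cambium, phloem, epidermis, stomatal lineage, root endodermis, root cap, root hair and shoot meristem. Of 348 entries 341 matched the annotation by locus and symbol, 2 were kept under an older symbol (ERF109 and PGB1) and 5 were left out. Members called in each direction were counted over all genes tested and adjusted over the list alone. The 21 lists with more than 1 measured member were tested against other genes with camera at a preset correlation of 0.01, adjusted over lists and times within mock against T0 and within NPA against mock. An estimated correlation and fry, which tests whether the members of a list move on balance one way without comparing them with other genes, were alternatives. Named genes were 15 fixed regulators and markers, the 3 highest and 3 lowest fold changes per comparison, and up to 4 called members per list with the largest changes (or 2 with the smallest p). Of the fixed genes 1 is not reported here. The 3 highest and lowest needed an adjusted p under 0.05, libraries that do not overlap, a mean TPM of at least 10 in the higher group and a symbol.

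Alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, TMM factors computed on the TPM values, quantile normalization, rescaling without organelle genes or without the 20 highest genes, no trend, a fit to the libraries compared alone, a replicate block, a minimum log2 fold change of 1, and each library left out in turn. Chosen after the data were seen were 2 sets of clock covariates, a replicate block crossed within times, and calls kept without each T0 library. Where a left-out library leaves a group with 1 library, that sample is assumed to vary like the other groups.

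The test was tried on simulated data with the real means and spread, scored on 200 changed genes of 20654. For NPA against mock at 6 h it recovered 56 of 100 genes changed by a log2 of 1 and 95 of 100 changed by 2, with 13 false calls, and at 5 d 60 and 92 with 12 false calls. For mock at 12 h against 6 h it recovered 59 and 89 with 8 false calls. For the mean over times 198 of 200 were recovered with 19 false calls, and for the difference between times 166 with 17. Of 21 lists the single moved list was called and 0 of the others. Noise was drawn apart for each gene, so correlation within lists, on which list calls rest, was not tried. TMM factors returned a known ratio of 2 for a library against its values times 2. With no gene changed in mock at 6 h against T0 and the T0 pair's spread given to T0 alone, 555 were called. With a pooled spread 0 were. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.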

Results

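Gene expression was profiled in detached leaves of Arabidopsis thaliana, accession Columbia, which can form adventitious roots beside the wound. This process is called de novo root regeneration. Seedlings were raised for 12 d at 22 °C with 16 h of light and 8 h of dark per day. Blades of the first rosette leaf pair were severed from their petioles. The blades lay on sugar-free B5 medium in constant light, either with no addition (mock) or with N-1-naphthylphthalamic acid (NPA). NPA inhibits polar auxin transport, and the labels do not give its dose. RNA was taken from the tissue next to the wound at detachment (T0) and after 6 h, 12 h and 24 h and then daily from 2 d to 5 d. The 30 libraries formed 15 groups of 2: T0, mock at 7 times and NPA at the same 7 times. The values were TPM, each gene's share of the transcripts of its library, so the sequencing depth of each library is unknown. Of 37686 genes in the tables, between 17201 and 19288 reached 1 TPM in a library, and 20654 were tested. Levels are given as mean ± SD in TPM with n = 2. Differences are log2 fold changes ± SE on the log2(TPM + 1) scale, which understates the change of low genes. Nothing in the labels says that replicates came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical.

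The T0 libraries differed from each other more than any other replicate pair, most of all in genes of the circadian clock. CCA1 and LHY, which encode morning-expressed clock repressors, stood at 318 and 447 TPM in T0 replicate 1 and at 0.13 and 0.17 TPM in T0 replicate 2. The evening-expressed genes TOC1 and ELF4 stood at 2.25 and 0.11 TPM in replicate 1 and at 84.3 and 94.1 TPM in replicate 2. GRP7, a clock-regulated RNA-binding protein gene, stood at 39.3 and 2944 TPM. Of the 15 measured clock genes, 13 differed more than 2-fold between these libraries (8 higher and 5 lower in replicate 2). So did 18 of 23 wound and jasmonate genes, all 18 higher in replicate 2. Pearson's r of log2 values across genes, which are not independent replicates, was 0.888 for T0 and 0.964 to 0.988 for the other pairs. At 12 h CCA1 stood at 114 and 14.4 TPM in mock replicates 1 and 2, and at 8.45 and 136 TPM in NPA replicates 1 and 2.

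**Figure D1:**
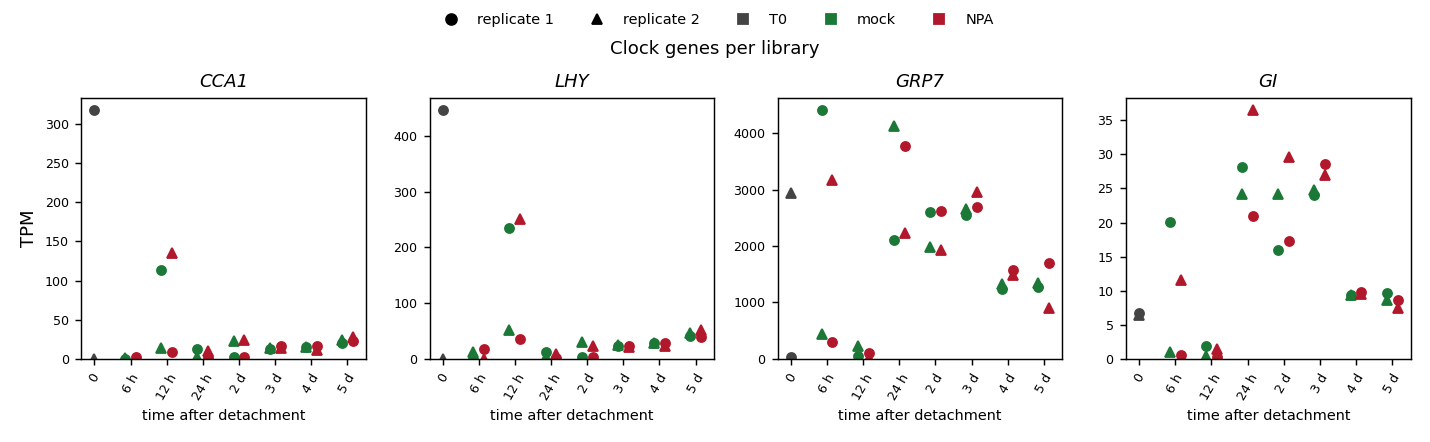
TPM of the clock genes CCA1, LHY, GRP7 and GI in each of the 30 libraries, by time after detachment, with circles for replicate 1 and triangles for replicate 2. CCA1 stands at 318 TPM in T0 replicate 1 and at 0.13 TPM in T0 replicate 2, and at 12 h replicates 1 and 2 stand at 114 and 14.4 TPM in mock but at 8.45 and 136 TPM with NPA.

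Mock against T0 asked what changes beside the wound after detachment. Light regime, medium and age changed too, with no control to part them. The largest rise among the genes named by rule was in EARLI1 (AT4G12480), a lipid-transfer-like protein gene, from 0.305 ± 0.431 to 482 ± 239 TPM at 6 h (log2 fold change 8.48 ± 0.37, adjusted p = 2.4e-11). It stood at 2921 ± 562 TPM at 2 d (log2 fold change 11.16 ± 0.37). Its relative AZI1, which acts in systemic immunity, rose from 0.275 ± 0.29 to 958 ± 78.6 TPM at 24 h (log2 fold change 9.57 ± 0.37, adjusted p = 3.75e-12). The extensin gene EXT4, of the cell wall, rose from 0.275 ± 0.12 to 1087 ± 139.7 TPM at 3 d (log2 fold change 9.73 ± 0.20, adjusted p = 8.02e-16). DFR and LDOX, enzymes of anthocyanin synthesis, rose to 745 ± 89.3 and 749 ± 129 TPM at 12 h (log2 fold changes 9.34 ± 0.85 and 9.30 ± 0.98). At 4 d they stood at 1197 ± 94.6 and 1004 ± 60.9 TPM. BAM5, a beta-amylase gene, rose from 0.275 ± 0.0919 to 317 ± 11.4 TPM at 6 h (log2 fold change 7.96 ± 0.77, adjusted p = 8.03e-07). The defensin gene PDF1.2 rose from 0.95 ± 0.948 to 2317 ± 389.7 TPM at 3 d (log2 fold change 10.30 ± 1.05, adjusted p = 6.62e-07). Among falling genes, GASA6, of the gibberellin-regulated GASA family, went from 215 ± 57.4 to 0.295 ± 0.0778 TPM at 6 h (log2 fold change -7.36 ± 0.73, adjusted p = 1.01e-06). The expansin gene EXPA8 fell from 87.3 ± 1.16 to 0.115 ± 0.0636 TPM (log2 fold change -6.31 ± 0.57). ACA1 (AT3G52720), a carbonic anhydrase gene, and BXL1, a beta-xylosidase gene, had log2 fold changes of -4.36 ± 0.60 and -3.85 ± 0.66 at 24 h, and DGR2 of -4.06 ± 0.46 at 12 h. From 2 d on the methionine sulfoxide reductase gene MSRB6 fell, from 84.1 ± 39.6 to 0.165 ± 0.00707 TPM at 4 d (log2 fold change -6.11 ± 0.39, adjusted p = 1.62e-09). RALFL32, a peptide gene, and NEET, an iron-sulfur protein gene, fell by 3 d (log2 fold changes -4.08 ± 0.63 and -4.03 ± 0.61). XTH17, a wall-modifying enzyme gene, was lower by 4 d (log2 fold change -4.15 ± 0.40) and the germin-like gene GER3 by 5 d (log2 fold change -5.78 ± 1.82, adjusted p = 0.0127). The GER3 call was lost without T0 replicate 2 or mock 5 d replicate 1. Near-identical members, such as EARLI1 and AZI1 or PDF1.2 and PDF1.3, can share reads, so their split is uncertain.

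More genes differed from T0 at 5 d than at 6 h. At 6 h 5479 genes were higher and 1285 lower than at T0, of which 1757 and 656 changed at least 2-fold. At 12 h the counts were 3504 higher and 1556 lower, at 24 h 6717 and 1855, and at 2 d 6906 and 1846. At 3 d they were 8238 and 1932, at 4 d 8226 and 1806, and at 5 d 8762 and 2244 (3900 and 985 of them at least 2-fold). The share of higher calls depended on scaling. It was 81.0% at 6 h and 79.6% at 5 d with TPM as deposited, 55.2% and 53.9% with TMM factors, and 50.3% and 45.1% with quantile normalization. At 12 h it was 69.2%, 54.9% and 46.4% in that order, at 24 h 78.4%, 51% and 46.9%, and at 2 d 78.9%, 53.1% and 48.1%. At 3 d it was 81.0%, 52.4% and 45.3%, and at 4 d 82.0%, 54.5% and 45.3%. The median log2 fold change of all tested genes against T0 was 0.21, 0.07, 0.26, 0.26, 0.34, 0.34 and 0.37 from 6 h to 5 d. Changes of list members are to be read against it. In an alternative chosen after the T0 libraries had been compared, 3385, 2782, 4352, 4688, 5820, 6190 and 7229 genes were called in the same direction both without T0 replicate 1 and without T0 replicate 2. The total was 4122 at 6 h without mock 6 h replicate 1 and 5629 at 24 h without mock 24 h replicate 2. When simulated genes, all unchanged between mock at 6 h and T0, were given the spread of the T0 pair, 555 of 20654 were called falsely. With many genes changed the p cutoff would be looser, and the noise was drawn apart for each gene. The 555 is thus no estimate of the false calls in the real comparison.

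**Figure D2:**
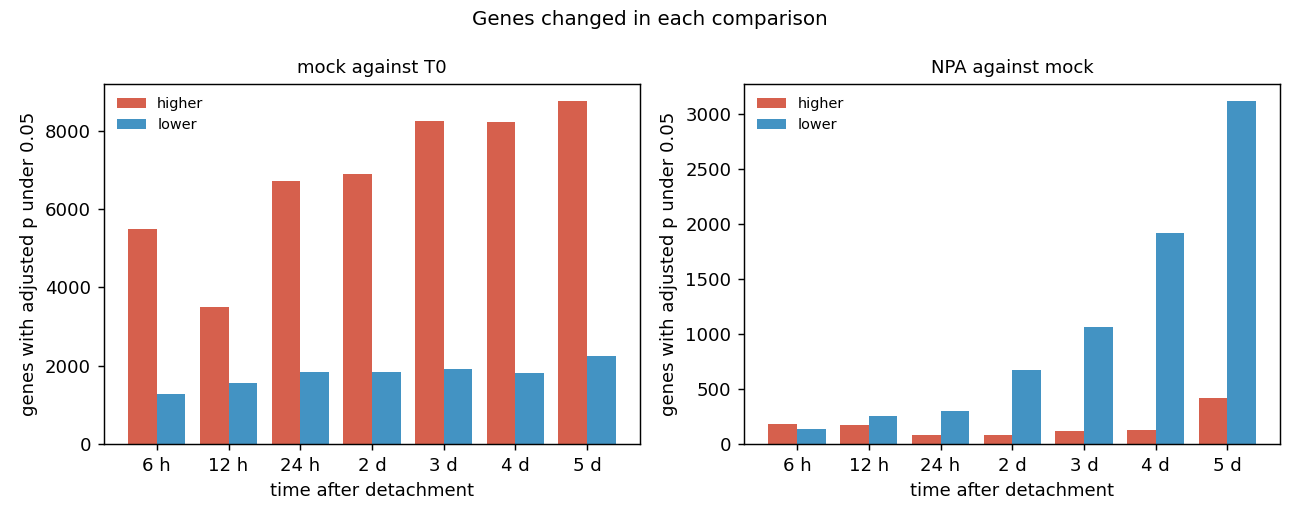
Number of genes higher (left bar of each pair) and lower (right bar) at each time, for mock against T0 and for NPA against mock, at a limma adjusted p under 0.05 with TPM as deposited. At 5 d 8762 genes were higher and 2244 lower in mock than at T0, and 422 were higher and 3118 lower with NPA than in mock, shares that TMM factors move to 53.9% and 44.6% higher.

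Some wound and jasmonate genes were higher at 6 h. Of 23 measured members, 15 rose and 0 fell at 6 h (15 and 0 adjusted over the list alone). At 12 h 11 rose (12 alone), at 24 h 9, and at later times 6 to 8, with 1 falling at 2 d. Higher in both fits that leave out a T0 library were 10 at 6 h, 9 at 12 h and 6 at 24 h. The vegetative storage protein gene VSP1 went from 3.39 ± 4.58 to 854 ± 263 TPM (log2 fold change 8.14 ± 0.97, adjusted p = 7.64e-06). LOX2, a lipoxygenase gene of jasmonate synthesis, went from 74.2 ± 96.4 to 3368 ± 551 TPM (log2 fold change 6.72 ± 0.84). AOC1, an allene oxide cyclase gene of the same pathway with near-identical copies, had a log2 fold change of 4.76 ± 0.42 at 12 h and still 4.67 ± 0.42 at 5 d. The members moved more than other genes at 6 h (camera adjusted p = 0.00105, and adjusted p = 0.637 with an estimated correlation) and at 12 h (camera adjusted p = 0.000897, and adjusted p = 0.631 with an estimated correlation). Without T0 replicate 1, in which 18 members were more than 2-fold lower than in replicate 2, the adjusted p was 0.0535 and 0.0793. Without T0 replicate 2 the list was also called at 24 h (adjusted p = 0.00647). At 3 d the median (0.51) and camera differed in sign, with no call. Salicylate and defence genes rose in up to 9 of 17 members, at 3 d (9 adjusted over the list alone; camera adjusted p = 0.163), and 5 in both fits that leave out a T0 library. Without T0 replicate 1 the list was called lower at 6 h (adjusted p = 0.0489). In this list 7 were more than 2-fold higher in T0 replicate 2 than in replicate 1. PR2, a glucanase gene, rose from 0.06 ± 0.0849 to 170.2 ± 12.8 TPM at 5 d (log2 fold change 7.34 ± 0.90, adjusted p = 2.73e-06). PAD3, of camalexin synthesis, rose by 4.38 ± 0.33 on the log2 scale. At 6 h 4 members fell, among them WRKY70 (log2 fold change -4.02 ± 0.82) and WRKY33 (log2 fold change -3.04 ± 0.65), both transcription factor genes. Of 15 ethylene genes, 8 rose at 24 h (8 alone, 4 in both fits that leave out a T0 library; camera adjusted p = 0.378), with ACS8, a synthesis gene, at 2.77 ± 0.18. The response factor genes ERF6 and ERF5 fell at 6 h (log2 fold changes -4.09 ± 0.75 and -2.7 ± 0.53).

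Some genes of auxin synthesis and response changed within hours. Of 12 measured synthesis genes, 6 rose at 6 h (7 adjusted over the list alone) and 5 or 6 at each later time, with 1 falling at 3 d and 2 at 5 d. Fewer rose in both fits that leave out a T0 library at 12 h and from 2 d on. TSA1 and ASB1, of tryptophan synthesis, had log2 fold changes of 3.54 ± 0.24 and 1.71 ± 0.19 at 6 h. ASA1 (AT5G05730, chromosome 5, 1719533 to 1722933), which feeds the same branch, rose from 26.2 ± 12.1 to 64.3 ± 10.9 TPM at 24 h (log2 fold change 1.33 ± 0.27, adjusted p = 0.000898). It was also called at 2 d and 3 d, calls lost without T0 replicate 1 (adjusted p = 0.317 and 0.47). YUC8, a flavin monooxygenase gene of the last step, rose at 5 d (log2 fold change 1.59 ± 0.20, adjusted p = 4.13e-06). YUC4 (AT5G11320, chromosome 5, 3611247 to 3613640) reached no more than 0.17 TPM and was not tested. GH3.3 (AT2G23170, chromosome 2, 9863855 to 9866562), an auxin-conjugating enzyme gene induced by auxin, rose from 0.33 ± 0.311 to 2.15 ± 0.488 TPM at 6 h (log2 fold change 1.26 ± 0.29, adjusted p = 0.00335). At a pseudocount of 5 the adjusted p of that rise was 0.143. GH3.3 stood at 29.9 ± 9.20 TPM at 2 d (log2 fold change 4.52 ± 0.29). Of 16 auxin response genes, 7 rose and 2 fell at 6 h, and 10 rose and 1 fell at 24 h, the same counts as adjusted over the list alone. In both fits that leave out a T0 library 4 rose at 6 h and 5 at 24 h. The repressor gene IAA14 fell at 6 h (log2 fold change -3.77 ± 0.58, adjusted p = 0.000112). IAA19 (AT3G15540, chromosome 3, 5264001 to 5265695) stood at 12.8 ± 5.36 TPM at T0 and 15.3 ± 2.95 at 6 h (log2 fold change 0.28 ± 0.53, adjusted p = 0.726), a difference within the spread. Of 14 transport genes, 4 rose and 3 fell at 5 d (4 and 3 adjusted over the list alone). ABCB4, an exporter gene, rose by 2.63 ± 0.18 on the log2 scale. LAX1, an influx carrier gene, fell by 5 d (log2 fold change -1.58 ± 0.24). With all libraries no auxin list differed from other genes at any time (lowest camera adjusted p = 0.0793, auxin synthesis at 24 h). Without T0 replicate 1 auxin synthesis was called higher at 6 h (adjusted p = 0.0217) and 24 h (0.0105) and auxin response at 12 h (0.0371). Medians and camera differed in sign for auxin response at 6 h and 4 d and for transport at 5 times. ERF109 (AT4G34410, chromosome 4, 16451876 to 16453260), a wound-responsive factor gene, stood at 1.02 ± 1.39 TPM at T0 and 0.97 ± 0.806 at 6 h (log2 fold change 0.09 ± 0.57, adjusted p = 0.936) and passed no comparison.

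By 5 d 11 of 15 measured root founder and primordium genes were higher. WOX11 (AT3G03660, chromosome 3, 889166 to 892229), a homeobox gene of founder cell formation, was listed at 0 in both T0 libraries. It stood at 0.485 ± 0.177 TPM at 6 h, 1.3 ± 0.332 at 12 h, 3.01 ± 1.32 at 24 h and 8.48 ± 1.82 at 4 d. At 4 d it differed from T0 by 3.23 ± 0.20 on the log2(TPM + 1) scale (adjusted p = 9.67e-10). Its call at 6 h (adjusted p = 0.037) was lost without either T0 library (adjusted p = 0.102 and 0.0744) and without either mock library (0.0591 and 0.198). LBD16 (AT2G42430, chromosome 2, 17663353 to 17665337), a lateral organ boundaries gene, rose from 0.04 TPM in each T0 library to 3.5 ± 1.42 at 6 h (log2 fold change 2.08 ± 0.22, adjusted p = 2.6e-06). It stood at 12.4 ± 0.926 TPM at 5 d (log2 fold change 3.69 ± 0.22, adjusted p = 4.36e-10). WOX7 (AT5G05770, chromosome 5, 1734427 to 1734855) and WOX5 (AT3G11260, chromosome 3, 3527280 to 3528440), homeobox genes, were listed at 0 at T0. They rose from 3 d on, to 7.83 ± 1.25 TPM (adjusted p = 9.63e-08) and 2.1 ± 1.01 TPM (adjusted p = 7.33e-05) at 5 d. The WOX5 call at 3 d was lost without T0 replicate 1 (adjusted p = 0.0591) and without mock replicate 2 (0.235). PLT3, a root meristem AP2 factor gene, rose from 1.20 ± 0.141 to 16.9 ± 4.03 TPM at 5 d (log2 fold change 3.00 ± 0.20, adjusted p = 1.68e-09). Of the 15 measured list members, 5 rose at 6 h, 9 at 3 d and 11 at 5 d (11 adjusted over the list alone). Up to 2 fell, among them SCR at 24 h (log2 fold change -1.19 ± 0.33). This call was lost without T0 replicate 1 (adjusted p = 0.222) or mock 24 h replicate 1 (0.0723). The list moved more than other genes at 4 d (camera adjusted p = 0.0199, and adjusted p = 0.521 with an estimated correlation) and 5 d (camera adjusted p = 0.0116, and adjusted p = 0.451 with an estimated correlation). With genes of mean TPM of at least 5 alone the median turned to -0.62 at 4 d and -0.74 at 5 d with no call. Without T0 replicate 2 the adjusted p was 0.206 and 0.12. Below the expression limit, LBD29 (AT3G58190) reached 0.97 ± 0.113 TPM in mock at 5 d, PLT2 (AT1G51190) 0.825 ± 0.898 and PLT1 (AT3G20840) 0.4 ± 0.354. WOX12 (AT5G17810) reached no more than 0.16 TPM in any library.

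Of 35 cell division genes 28 were higher at 5 d. Of 35 measured members, 3 fell at 6 h (2 adjusted over the list alone) and 1 at 12 h. At 24 h 14 rose (12 alone), 22 at 2 d (23 alone) and 28 at 5 d (28 alone). In both fits that leave out a T0 library 3, 10 and 20 rose at these times. In T0 replicate 2 the list stood above replicate 1 by a median of 0.78 on the log2 scale. TSO2, a ribonucleotide reductase gene of S phase, fell at 6 h (log2 fold change -1.51 ± 0.27). The replication licensing gene MCM3 rose by 24 h (log2 fold change 1.01 ± 0.22, adjusted p = 0.00173). CYCB1;1 (AT4G37490, chromosome 4, 17621886 to 17624308), a mitotic cyclin gene, rose from 1.35 ± 0.877 to 4.19 ± 0.283 TPM at 2 d (log2 fold change 1.19 ± 0.25). It stood at 7.50 ± 2.34 TPM at 5 d (log2 fold change 1.88 ± 0.25, adjusted p = 6.28e-06), when CYCB2;2 had a log2 fold change of 1.93 ± 0.22. The list stood below other genes at 6 h (camera adjusted p = 2.64e-05, and adjusted p = 0.621 with an estimated correlation). It stood above them at 2 d (camera adjusted p = 0.00758, and adjusted p = 0.836 with an estimated correlation) and 5 d (camera adjusted p = 0.00138, and adjusted p = 0.745 with an estimated correlation). The call at 6 h was lost without T0 replicate 2 (adjusted p = 0.172). The calls at 2 d, 4 d and 5 d were lost without T0 replicate 1 (adjusted p = 0.296, 0.136 and 0.0514). At mean TPM of at least 5 the calls from 2 d to 5 d were lost (adjusted p = 0.207, 0.0581, 0.124 and 0.0836). A call was gained at 12 h, lower, without T0 replicate 1 (adjusted p = 0.00439), and at 24 h, higher, without T0 replicate 2 (0.0153). All 3 measured root endodermis markers rose by 5 d (camera adjusted p = 0.0333, and adjusted p = 0.355 with an estimated correlation). MYB36, a master regulator gene of the Casparian strip, was listed at 0 at T0 and stood at 7.89 ± 0.955 TPM (difference 3.15 ± 0.13 on the log2(TPM + 1) scale, adjusted p = 2.27e-12). CASP1, a Casparian strip membrane protein gene, and ESB1 rose by 1.14 ± 0.17 and 0.99 ± 0.17 on the log2 scale. The list call was lost without T0 replicate 1 (adjusted p = 0.0556) or 2 (0.0652) and at a pseudocount of 0.1 (0.0857). CUC1, a boundary gene and the only measured shoot meristem marker, rose from 0.04 ± 0 to 1.58 ± 0.12 TPM at 5 d (log2 fold change 1.31 ± 0.16, adjusted p = 3.28e-06). No marker of root cap or root hair passed the expression limit.

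Many photosynthesis and cytokinin genes were lower. Of 34 measured photosynthesis genes, 11 fell at 6 h (13 adjusted over the list alone), 13 at 24 h and 23 at 5 d (23 alone). In both fits that leave out a T0 library 4, 6 and 14 were lower at these times. Of the 34 genes 8 were more than 2-fold lower in T0 replicate 2 than in replicate 1. RBCS3B, a Rubisco small subunit gene, had a log2 fold change of -2.13 ± 0.22 at 5 d and PSAN, of photosystem I, of -1.75 ± 0.27. RBCS and LHCB copies are near-identical and their split is uncertain. The list stood below other genes at 6 h (camera adjusted p = 1.76e-12, and adjusted p = 0.163 with an estimated correlation) and 5 d (camera adjusted p = 9.06e-14, and adjusted p = 0.163 with an estimated correlation). Quantile normalization ended the calls from 24 h to 4 d (adjusted p = 0.316, 0.194, 0.26 and 0.084) and turned the 12 h median to 0.0248. The 12 h call was also lost without T0 replicate 1 (adjusted p = 0.877), without mock replicate 2 (0.182) and with TMM factors (0.0988). Of 13 cytokinin genes, 8 fell at 6 h (8 alone) and 7 or 8 at each later time (camera adjusted p = 8.85e-08, and adjusted p = 0.163 with an estimated correlation at 6 h). The response regulator gene ARR4 went from 50.8 ± 2.25 to 4.57 ± 0.983 TPM at 2 d (log2 fold change -3.23 ± 0.21, adjusted p = 4.16e-09), and ARR7 had a log2 fold change of -2.85 ± 0.37 at 6 h. The synthesis gene IPT7 rose, at 2.81 ± 0.16 at 5 d. TMM scaling ended the cytokinin call at 5 d (adjusted p = 0.0638), as did a mean TPM of at least 5 (0.0621). Of 8 hypoxia genes, 7 rose at 5 d (7 alone; camera adjusted p = 0.00684, and adjusted p = 0.163 with an estimated correlation). They were led by ADH1, of ethanol fermentation, which rose from 2.68 ± 0.0141 to 17.1 ± 1.53 TPM (log2 fold change 2.29 ± 0.23, adjusted p = 2.87e-07). Up to 11 of 17 senescence genes rose, at 5 d (11 alone; camera adjusted p = 0.458), with SAG13 at 3.80 ± 0.67 and the NAC factor gene ORS1 at 2.16 ± 0.24. Of 15 abscisic acid genes, 2 rose and 5 fell at 5 d (camera adjusted p = 0.0121, and adjusted p = 0.41 with an estimated correlation), among them the phosphatase gene HAI1 (log2 fold change -3.24 ± 0.59). TMM scaling ended this list call (adjusted p = 0.0786), as did quantile normalization (0.175) and leaving out T0 replicate 2 (0.0632). At 3 d the list median (0.05) and its test (adjusted p = 0.046, lower, and 0.451 with an estimated correlation) differed in sign, and TMM scaling ended the call (0.225). Among 15 clock genes only PRR5 was called, higher at 24 h (log2 fold change 2.84 ± 0.85, adjusted p = 0.0131), 2 d and 3 d (0 adjusted over the list alone). Without T0 replicate 1 its adjusted p at 24 h was 0.275. The list medians were 1.35, 1.20, 1.55, 0.44 and 0.88 from 24 h on, against a camera direction of lower and no call. Of 14 ribosome genes, 2 were higher at 6 h and 2 at 5 d, among them the fibrillarin gene FIB2 (log2 fold change 1.45 ± 0.43, adjusted p = 0.00915). FIB2 lost its call with TMM factors (adjusted p = 0.0573) or without mock 5 d replicate 2 (0.107). No call was made for the list (camera adjusted p = 0.999 at 5 d).

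Markers of vascular and surface tissues changed in both directions. All 11 measured xylem markers fell by 2 d (11 adjusted over the list alone; camera adjusted p = 7.44e-10, and adjusted p = 0.189 with an estimated correlation), and 5 were lower at 5 d. At 2 d the laccase gene LAC4 fell from 11.9 ± 1.36 to 1.93 ± 0.184 TPM (log2 fold change -2.13 ± 0.23, adjusted p = 1.84e-06). The xylem protease genes XCP1 and XCP2 had log2 fold changes of -1.73 ± 0.35 and -1.89 ± 0.27. Cambium markers rose, 5 of 6 at 6 h and all 6 at 4 d (6 alone; camera adjusted p = 0.0119, and adjusted p = 0.41 with an estimated correlation). WOX4, which maintains the cambium, rose from 2.90 ± 0.544 to 16.4 ± 1.80 TPM (log2 fold change 2.16 ± 0.21, adjusted p = 2.34e-07), and SMXL5 by 2.36 ± 0.26 on the log2 scale. The cambium calls at 6 h, 2 d and 5 d were lost without T0 replicate 1 (adjusted p = 0.0998, 0.0838 and 0.074), as was that at 12 h (0.231). Those at 6 h, 2 d and 5 d were lost without T0 replicate 2 too (0.0569, 0.0632 and 0.0569). Of 6 phloem markers, 3 rose at 5 d with no call for the list (camera adjusted p = 0.991), among them PP2-A1, a phloem lectin gene (log2 fold change 1.71 ± 0.20). SEOR1, a sieve element protein gene, fell at 24 h (log2 fold change -1.01 ± 0.24). Of 4 epidermis markers, 3 fell by 4 d (3 alone; camera adjusted p = 0.000283, and adjusted p = 0.227 with an estimated correlation), with the homeobox gene ATML1 at -1.43 ± 0.19. The epidermis calls at 6 h, 12 h and 24 h were lost without T0 replicate 2 (adjusted p = 0.206, 0.169 and 0.0944), and those at 6 h and 12 h without T0 replicate 1 too (0.0556 and 0.0793). Of 7 stomatal lineage genes, 5 fell by 5 d (6 alone; camera adjusted p = 8.36e-05, and adjusted p = 0.212 with an estimated correlation). TMM, a receptor-like protein gene, fell from 9.17 ± 0.325 to 0.585 ± 0.318 TPM (log2 fold change -2.7 ± 0.32, adjusted p = 2.12e-06). SPCH, the initiating factor gene, had a log2 fold change of -1.43 ± 0.26. The stomatal calls at 2 d and 3 d were lost without T0 replicate 1 (adjusted p = 0.219 and 0.0504). At mean TPM of at least 5 those from 2 d to 5 d were lost (0.432, 0.255, 0.109 and 0.0554). With no list call, medians were above 0 and camera directions lower for salicylate, xylem and ethylene genes at 12 h or before. The same held for ribosome genes at 24 h and from 3 d, endodermis at 24 h, phloem at 3 d and ethylene at 5 d.

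**Figure D3:**
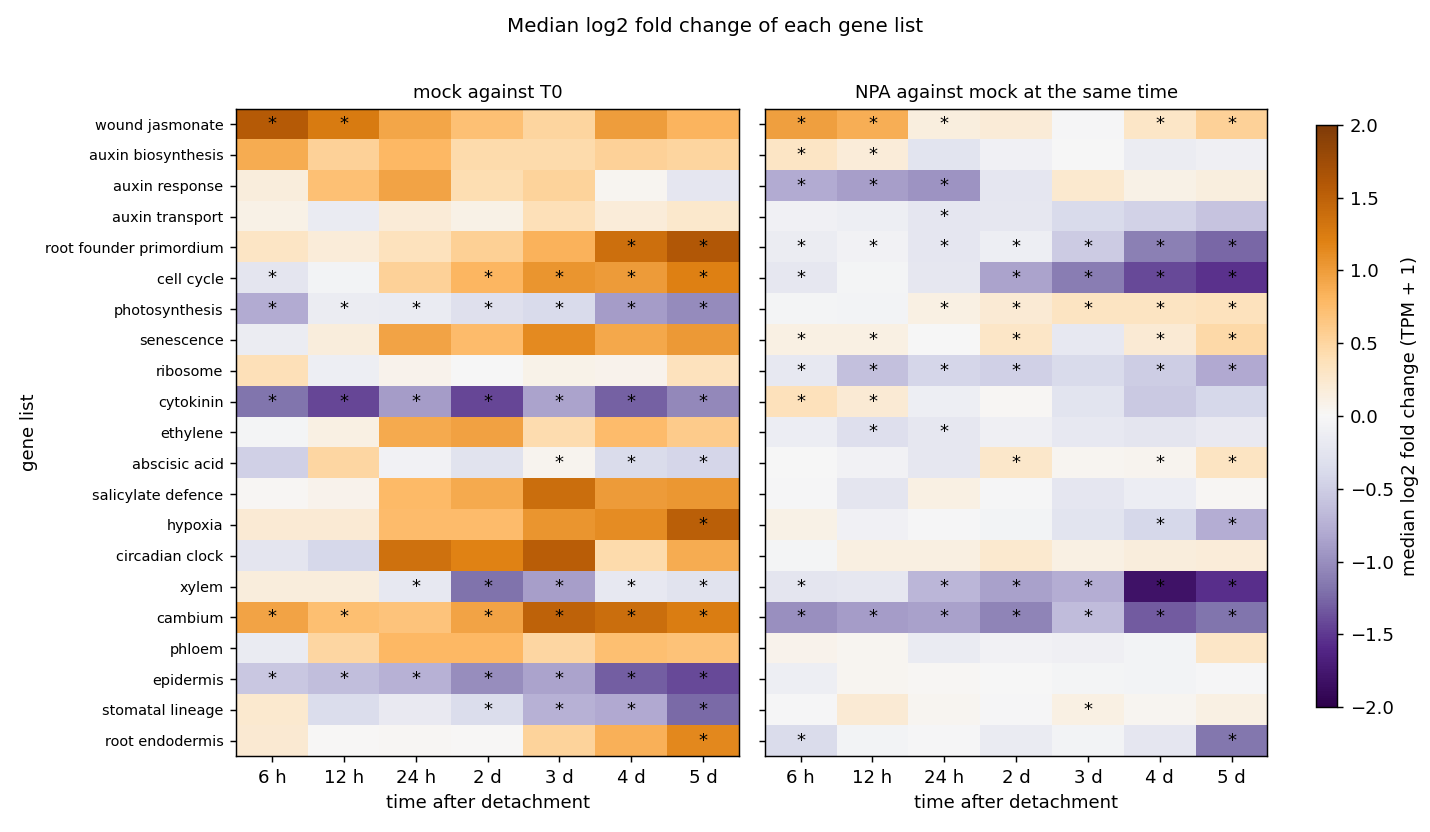
Median log2 fold change (colour, from -2 to 2) of the measured members of 21 gene lists at each of the 7 times, for mock against T0 and for NPA against mock, with an asterisk where the camera adjusted p was under 0.05 at a preset correlation. The xylem median is -1.19 in mock against T0 at 2 d and the cell cycle median -1.53 with NPA at 5 d, and with an estimated correlation only cambium with NPA at 6 h keeps its call.

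Successive times of the mock course asked when expression turned. From 6 h to 12 h 416 genes rose and 1428 fell, and from 12 h to 24 h 2195 rose and 853 fell. In the earlier step the repressor gene IAA14 rose (log2 fold change 2.95 ± 0.58) and TSA1 fell (log2 fold change -1.70 ± 0.24, adjusted p = 0.000586). CYP94B3, which inactivates jasmonate, fell as well (log2 fold change -2.12 ± 0.27). In the later step GH3.3 rose (log2 fold change 2.03 ± 0.29, adjusted p = 0.00108), with the licensing gene MCM2 (log2 fold change 0.86 ± 0.21), while RBCS2B fell (log2 fold change -1.78 ± 0.43). The clock-controlled genes GRP7 and GI rose in this step (log2 fold changes 4.79 ± 1.46 and 3.75 ± 0.84). With clock components over all libraries as covariates, chosen after the data were seen, 32 genes were called, against 3048 without, in the 12 h to 24 h step. None of the 56 called list members kept its call there. The fold change of 30 stayed within 1.5 times its value, that of 18 was smaller and that of 8 changed sign. The median SE went from 0.24 to 0.27. With so few genes called, the adjusted p of a given change was higher. Among those that stayed were GH3.3 at 1.84 ± 0.48 (adjusted p = 0.107), the haemoglobin gene PGB1 at 1.75 ± 0.42 (1.70 ± 0.26 before), the senescence factor gene ORE1 at 1.39 ± 0.48 (1.41 ± 0.39 before) and the cyclin gene CYCB2;4 at 1.18 ± 0.24 (0.86 ± 0.23 before). The log2 fold change fell to 0.34 ± 0.18 for MCM2 and -0.15 ± 0.19 for RBCS2B. It turned to -0.18 ± 0.25 for GRP7 (adjusted p = 0.812) and -0.03 ± 0.52 for GI (0.991). In this step MCM2, RBCS2B, GRP7 and GI also lost their calls with 1 library left out (without mock 24 h replicate 2, adjusted p = 0.145, 0.069, 0.203 and 0.0706). In the earlier step 16 of 22 list members kept their calls with these components, IAA14 at 1.70 ± 0.46 (adjusted p = 0.0257). IAA14 lost its call without mock 6 h replicate 1 (0.11). From 24 h to 2 d 46 genes rose and 39 fell. Among the latter were the xylem genes XCP1 (log2 fold change -1.84 ± 0.35, adjusted p = 0.0228) and LAC17 (log2 fold change -1.65 ± 0.28). Both were lost with any 1 of the 4 libraries left out (adjusted p up to 0.285 and 0.114). From 2 d to 3 d 252 rose and 36 fell. ARR4 (log2 fold change 1.3 ± 0.21, adjusted p = 0.00262) and CUC1 (log2 fold change 1.08 ± 0.16) were among the risers, the former lost without mock 2 d replicate 1 (adjusted p = 0.0561). From 3 d to 4 d 287 rose and 121 fell. Higher were MYB36 (log2 fold change 1.55 ± 0.13, adjusted p = 4.36e-07) and PUCHI, a primordium AP2 factor gene (log2 fold change 1.07 ± 0.16). From 4 d to 5 d 205 genes changed, of which 4 fell. Among the risers were LBD33, a partner of LBD18 in primordia (log2 fold change 1.15 ± 0.12, adjusted p = 2.55e-05), and CASP1 (log2 fold change 1.05 ± 0.17). Both were lost at a pseudocount of 0.1 (adjusted p = 0.0748 and 0.648). TMM factors gave 747 higher and 922 lower for 12 h against 6 h (44.8% higher, against 22.6% as deposited). For 24 h against 12 h they gave 830 and 1461 (36.2% against 72.0%). Quantile normalization gave 39.1% for the earlier of these, 46.2% for the later and 52.0% for 4 d against 3 d, against 70.3% as deposited. Left-out libraries moved every step by over 1.5 times, most for 12 h (288 genes without mock 6 h replicate 1) and 24 h (296 without mock 24 h replicate 2). The 2 d step fell to as few as 17 (without mock 24 h replicate 1).

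The comparison of NPA with mock at the same time asked which of these changes depend on auxin transport. By 5 d 11 of 15 root founder genes were lower with NPA than in mock. WOX11 was listed at 0 in all 14 NPA libraries. Against 8.48 ± 1.82 TPM in mock at 4 d it differed by -3.23 ± 0.20 on the log2(TPM + 1) scale (adjusted p = 5.9e-09). It was called lower from 12 h on (adjusted p = 0.00228) and not at 6 h (adjusted p = 0.34). LBD16 stood at 0.325 ± 0.276 TPM with NPA against 3.5 ± 1.42 at 6 h (log2 fold change -1.74 ± 0.22, adjusted p = 0.000141). At 5 d it stood at 0.78 ± 0.212 against 12.4 ± 0.926 TPM (log2 fold change -2.92 ± 0.22, adjusted p = 3.16e-08). WOX7 was listed at 0 with NPA at 5 d against 7.83 ± 1.25 TPM in mock (difference -3.13 ± 0.29, adjusted p = 3.62e-07). WOX5 stood at 0.39 ± 0.0141 against 2.1 ± 1.01 TPM (log2 fold change -1.12 ± 0.27, adjusted p = 0.00629). PLT3 fell from 16.9 ± 4.03 to 1.38 ± 0.0778 TPM at 5 d (log2 fold change -2.89 ± 0.20, adjusted p = 9.48e-09). GATA23, which marks founder cells, was lower at 6 h (log2 fold change -1.41 ± 0.27). This call was lost without NPA replicate 2 (adjusted p = 0.157) or without either mock library. LBD29 was listed at 0 with NPA at 5 d. Of the 15 measured members 3 were lower at 6 h, 7 at 3 d and 11 at 5 d (12 adjusted over the list alone). By limma none was higher, and at 5 d 12 members were under an unadjusted p of 0.05. The list stood below other genes at 6 h (camera adjusted p = 0.000159, and adjusted p = 0.205 with an estimated correlation). So it did at 4 d (camera adjusted p = 3.71e-11, and adjusted p = 0.0618 with an estimated correlation) and 5 d (camera adjusted p = 2.4e-10, and adjusted p = 0.0663 with an estimated correlation). The call was lost at mean TPM of at least 5 from 12 h on (adjusted p from 0.172 to 0.659), where most of these low genes are left out. At 12 h it was lost without NPA replicate 2 (0.18) or mock replicate 2 (0.0618). The call of WOX5 at 5 d was lost without mock replicate 2 (adjusted p = 0.166).

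**Figure D4:**
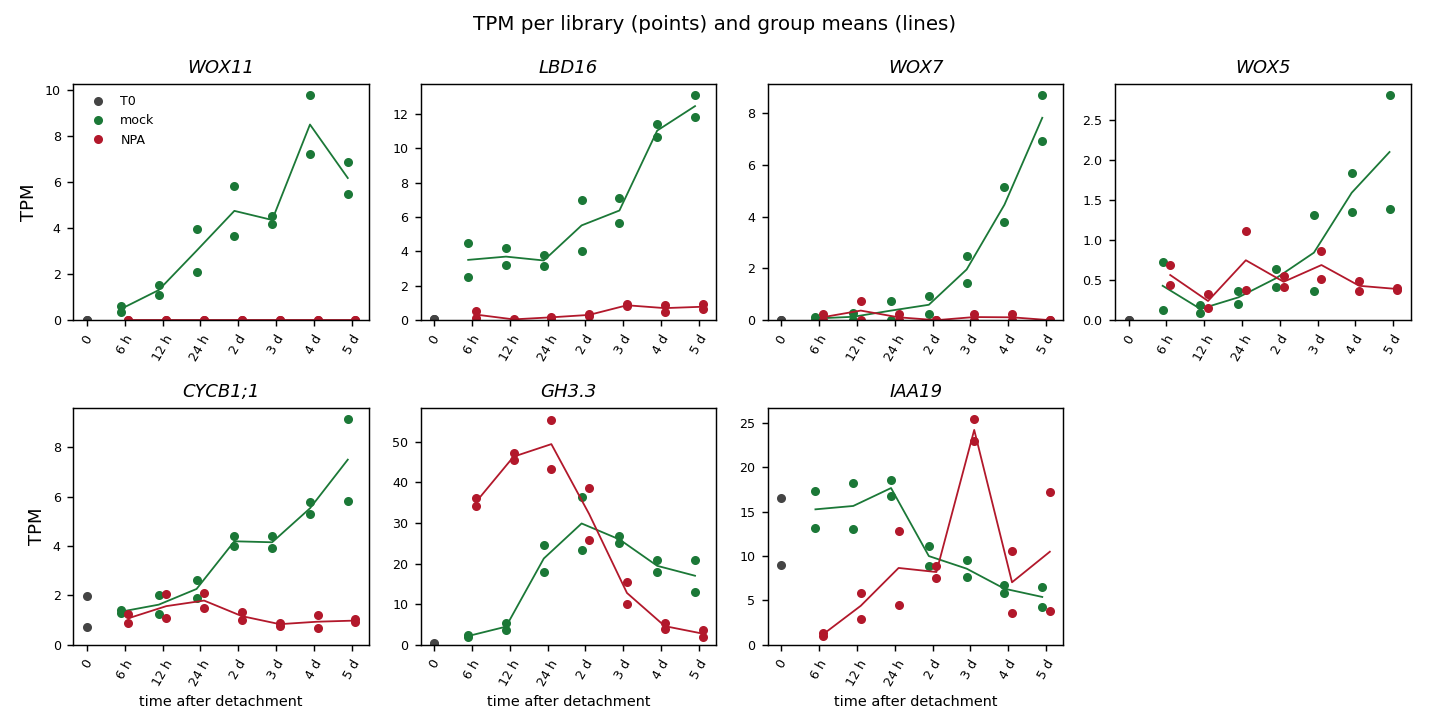
TPM of WOX11, LBD16, WOX7, WOX5, CYCB1;1, GH3.3 and IAA19 by time after detachment, with a point per library and lines through the group means of mock and NPA. WOX11 is listed at 0 in every NPA library against 8.48 TPM in mock at 4 d, and GH3.3 stands at 35.1 TPM with NPA against 2.15 in mock at 6 h but at 2.75 against 17.0 at 5 d.

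At 6 h of NPA 1 of 16 auxin response genes was higher and 6 were lower. GH3.3 rose from 2.15 ± 0.488 to 35.1 ± 1.43 TPM (log2 fold change 3.52 ± 0.29, adjusted p = 2.04e-06). IAA19 fell from 15.3 ± 2.95 to 1.18 ± 0.219 TPM (log2 fold change -2.90 ± 0.53, adjusted p = 0.00455). The repressor genes IAA5, IAA1 and IAA30 were lower (log2 fold changes -2.42 ± 0.32, -2.25 ± 0.33 and -2.01 ± 0.24). Of 16 members, 1 rose and 6 fell at 6 h (1 and 7 adjusted over the list alone; camera adjusted p = 4.5e-11, and adjusted p = 0.0526 with an estimated correlation). The counts were 1 and 5 at 12 h (camera adjusted p = 5.92e-05, and adjusted p = 0.126 with an estimated correlation) and 1 and 6 at 24 h (camera adjusted p = 4.63e-07, and adjusted p = 0.0911 with an estimated correlation). At mean TPM of at least 5 the 12 h call was lost (adjusted p = 0.115). From 3 d on IAA1 and GH3.5 were higher and GH3.2 lower. GH3.3 fell from 17.0 ± 5.56 to 2.75 ± 1.17 TPM at 5 d (log2 fold change -2.26 ± 0.29, adjusted p = 1.83e-05), when GH3.5 had risen by 2.17 ± 0.32. GH3.2 fell from 24.8 ± 1.32 to 0.03 ± 0 TPM at 4 d (log2 fold change -4.65 ± 0.45, adjusted p = 1.2e-06). LAX2, an auxin influx carrier gene, fell from 26.5 ± 6.00 to 1.19 ± 0.594 TPM at 6 h (log2 fold change -3.66 ± 0.37, adjusted p = 1.18e-05) and was lower at every time. At 5 d 7 of 14 transport genes were lower and 2 higher (8 and 2 alone; camera adjusted p = 0.247). The list was called at 24 h alone (camera adjusted p = 0.0429, and adjusted p = 0.462 with an estimated correlation), and not without NPA replicate 1 (0.121) or mock replicate 1 (0.0952). Auxin synthesis genes stood above others at 6 h (camera adjusted p = 0.000151, and adjusted p = 0.0526 with an estimated correlation). CYP79B2, of indole glucosinolate synthesis, was called higher (log2 fold change 1.11 ± 0.26), though not with any 1 of the 4 libraries left out (adjusted p up to 0.385). ASA1 stood at 77.8 ± 17.2 against 40.8 ± 15.4 TPM (log2 fold change 0.95 ± 0.27, adjusted p = 0.12). YUC8 fell by 5 d (log2 fold change -1.69 ± 0.20, adjusted p = 7.67e-06). IAA19 lost its call without mock 6 h replicate 2 (adjusted p = 0.0753) or NPA 6 h replicate 1 (0.0666). GH3.3 lost its small rise at 24 h (log2 fold change 1.19 ± 0.29, adjusted p = 0.0448) with any 1 of the 4 libraries left out.

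Further genes with large changes in the hours after NPA were of several kinds. Rap2.6L (AT5G13330, chromosome 5, 4271730 to 4274674), an ERF factor gene of wound repair, rose from 2.59 ± 0.297 to 55.0 ± 17.9 TPM at 6 h (log2 fold change 3.93 ± 0.23, adjusted p = 2.07e-08). The trehalose phosphate phosphatase gene TPPD rose from 0.44 ± 0.0566 to 20 ± 7.95 TPM (log2 fold change 3.81 ± 0.39). Both turned lower by 5 d (log2 fold changes -1.19 and -2.03). CYP81D11 (AT3G28740, chromosome 3, 10788698 to 10790553), a cytochrome P450 gene induced by foreign chemicals and jasmonate, rose from 3.65 ± 1.62 to 88.5 ± 55.2 TPM at 12 h (log2 fold change 4.16 ± 0.40, adjusted p = 8.45e-06). At 5 d the change was from 1.89 ± 0.0212 to 73.2 ± 24.6 TPM (log2 fold change 4.64 ± 0.40, adjusted p = 1.6e-07). GolS1, of galactinol synthesis, and CYP94B1, which oxidizes jasmonoyl-isoleucine, rose at 12 h (log2 fold changes 3.96 ± 0.73 and 3.41 ± 0.27). The nitrate transporter gene NRT2.6 was higher at 24 h (log2 fold change 2.99 ± 0.49, adjusted p = 0.00212) and 2 d (log2 fold change 3.66 ± 0.49). ACL5, a thermospermine synthase gene of xylem, fell from 28.9 ± 3.23 to 2.81 ± 0.643 TPM at 6 h (log2 fold change -2.98 ± 0.26, adjusted p = 3.01e-06). ATC, a floral repressor gene, was lower at 24 h (log2 fold change -4.49 ± 0.66, adjusted p = 0.000869). The defensin genes PDF1.2 and PDF1.3 and the root peptide gene RGF6 were lower at 12 h (log2 fold changes -4.87 ± 1.05, -3.35 ± 0.81 and -3.24 ± 0.77). AACT1 (AT5G61160), an acyltransferase gene, was lower at 24 h (log2 fold change -3.77 ± 0.67). Of 23 wound and jasmonate genes, 4 were higher at 6 h (5 adjusted over the list alone; camera adjusted p = 7.61e-17, and adjusted p = 0.125 with an estimated correlation). At 12 h 3 were higher (camera adjusted p = 1.42e-08, and adjusted p = 0.266 with an estimated correlation). The repressor genes JAZ10 and JAZ8 had log2 fold changes of 2.7 ± 0.34 and 2.1 ± 0.28 at 6 h. The cytokinin response regulator gene ARR4 was higher at 6 h, from 5.70 ± 1.14 to 35.9 ± 5.13 TPM (log2 fold change 2.46 ± 0.21, adjusted p = 2.26e-06), and lower at 5 d (log2 fold change -1.3 ± 0.21, adjusted p = 0.000191). Of 13 cytokinin genes 1 was higher at 6 h (camera adjusted p = 3.14e-05, and adjusted p = 0.0983 with an estimated correlation) and 5 lower at 5 d (camera adjusted p = 0.221). The 12 h calls of PDF1.2 and PDF1.3 were lost with any 1 of the 4 libraries left out (adjusted p up to 0.128 and 0.219). RGF6 lost its call with any but NPA replicate 1 left out (adjusted p up to 0.214), and GolS1 without replicate 2 of NPA or mock (0.0522 and 0.0697). At 24 h AACT1 lost its call without NPA replicate 1 (0.0721) or mock replicate 2 (0.125), and NRT2.6 without NPA replicate 1 (0.0544).

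With NPA 27 of 35 cell cycle genes were lower at 5 d, 10 of 11 xylem markers at 4 d and all 6 cambium markers at 5 d. CYCB1;1 stood at 0.98 ± 0.0707 TPM against 7.50 ± 2.34 in mock at 5 d (log2 fold change -2.07 ± 0.25, adjusted p = 7.23e-06). CDKB2;2, a mitotic kinase gene, had a log2 fold change of -1.83 ± 0.20 at 4 d. Of 35 cell cycle genes, 16 were lower at 2 d (23 adjusted over the list alone; camera adjusted p = 1.37e-20, and adjusted p = 0.127 with an estimated correlation) and 27 at 5 d (30 alone; camera adjusted p = 1.37e-15, and adjusted p = 0.195 with an estimated correlation). The list stood below other genes at 6 h as well, with 1 member called (camera adjusted p = 0.00198, and adjusted p = 0.699 with an estimated correlation). This call was lost without NPA replicate 2 (adjusted p = 0.104). At 24 h none was called by limma and 3 had an unadjusted p under 0.05 (fry adjusted p = 0.42). The xylem protease gene XCP1 fell from 32.4 ± 0.53 to 2.23 ± 1.01 TPM at 4 d (log2 fold change -3.41 ± 0.35, adjusted p = 2.03e-06), and the cellulose synthase gene CESA8 had a log2 fold change of -2.15 ± 0.21. At 4 d 10 of 11 xylem markers were lower (11 alone; camera adjusted p = 4.14e-14, and adjusted p = 0.0663 with an estimated correlation). With no member called, the xylem list stood below other genes at 6 h (camera adjusted p = 0.0417, and adjusted p = 0.601 with an estimated correlation) and 24 h (camera adjusted p = 4.32e-07, and adjusted p = 0.156 with an estimated correlation). The 6 h call was lost without NPA replicate 2 (adjusted p = 0.966) or mock replicate 1 (0.0514) or 2 (0.187). It was lost at mean TPM of at least 5 (0.184), a pseudocount of 0.1 (0.179) and with quantile normalization (0.0868) too. Cambium markers were lower at every time, 4 of 6 at 6 h (6 alone; camera adjusted p = 3.6e-14, and adjusted p = 0.0354 with an estimated correlation) and all 6 at 5 d (camera adjusted p = 5.24e-05, and adjusted p = 0.123 with an estimated correlation). The vascular homeobox gene ATHB8 fell from 25.4 ± 1.92 to 8.29 ± 1.29 TPM at 6 h (log2 fold change -1.51 ± 0.17, adjusted p = 4.54e-05). The endodermis regulator gene MYB36 fell from 7.89 ± 0.955 to 0.43 ± 0.198 TPM at 5 d (log2 fold change -2.64 ± 0.13, adjusted p = 1.02e-10), and all 3 markers were lower (camera adjusted p = 0.000269, and adjusted p = 0.0911 with an estimated correlation). PR-1-LIKE (AT2G19990, chromosome 2, 8629857 to 8630688), of the pathogenesis-related family, fell from 50 ± 3.02 to 0.24 ± 0.17 TPM at 5 d (log2 fold change -5.37 ± 0.17, adjusted p = 5.95e-13). The beta-glucosidase gene PYK10 fell from 71.1 ± 7.36 to 3.62 ± 0.354 TPM at 3 d (log2 fold change -3.96 ± 0.38, adjusted p = 3.1e-06). AGP31, an arabinogalactan protein gene, GRP9, of a glycine-rich protein, and GASA5 were lower too (log2 fold changes -4.57 ± 0.44 at 4 d, and -5.11 ± 0.40 and -4.59 ± 0.31 at 5 d). Higher with NPA were DES1, a cysteine desulfhydrase gene, at 2 d (log2 fold change 2.66 ± 0.43), PELPK1, a proline-rich protein gene, at 3 d (log2 fold change 2.58 ± 0.20), and MAKR6 at 4 d (log2 fold change 2.79 ± 0.47). PELPK1 was lower later, with log2 fold changes of -1.44 at 4 d and -2.86 at 5 d. At 5 d NAS2, of nicotianamine synthesis (log2 fold change 2.89 ± 0.28), and HSPRO2 (log2 fold change 2.83 ± 0.85, adjusted p = 0.0284) were higher, the latter call lost without replicate 2 of NPA (adjusted p = 0.202) or mock (0.49).

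Some members of other lists differed with NPA. Of 14 ribosome genes, 11 were lower at 5 d (13 adjusted over the list alone; camera adjusted p = 0.000151, and adjusted p = 0.512 with an estimated correlation), among them FIB2 (log2 fold change -2.08 ± 0.43, adjusted p = 0.00232). Without mock replicate 2 FIB2 had an adjusted p of 0.061. At 6 h the list call was lost without mock replicate 1 (adjusted p = 0.889), where its median turned to 0.0074, and without NPA replicate 1 (0.878). Of 8 hypoxia genes, 6 were lower at 5 d (6 alone; camera adjusted p = 0.000939, and adjusted p = 0.0591 with an estimated correlation). The haemoglobin gene PGB1 fell from 11.3 ± 0.0707 to 2.48 ± 0.53 TPM (log2 fold change -1.83 ± 0.26, adjusted p = 5.21e-05). Photosynthesis genes stood above others from 24 h on (camera adjusted p = 3.32e-06, and adjusted p = 0.178 with an estimated correlation at 5 d). ATPC1, of the chloroplast ATP synthase, was the only member called (log2 fold change 0.30 ± 0.10, adjusted p = 0.0406). It was not called with any 1 of the 4 libraries left out (adjusted p up to 0.301). Quantile normalization ended the list call at each time (adjusted p = 0.193 at 5 d). At 24 h it was lost without mock replicate 2 (median -0.12, adjusted p = 0.467) or NPA replicate 2 (median -0.04, 0.0744). At 2 d it was lost without NPA replicate 2 (0.119). Of 17 senescence genes, 3 were higher at 5 d (4 alone; camera adjusted p = 0.000281, and adjusted p = 0.112 with an estimated correlation), with SEN1 (log2 fold change 2.78 ± 0.63, adjusted p = 0.00471). Of 15 abscisic acid genes 3 were higher (3 alone; camera adjusted p = 0.00357, and adjusted p = 0.208 with an estimated correlation), with the synthesis gene NCED3 (log2 fold change 2.06 ± 0.59, adjusted p = 0.0205). Without mock 5 d replicate 2 the adjusted p was 0.084 for SEN1 and 0.205 for NCED3. Without NPA 5 d replicate 2 it was 0.0995 and 0.255. Jasmonate genes were above others at 4 d and 5 d by camera with no member higher (adjusted p = 0.00148 at 5 d, and adjusted p = 0.597 with an estimated correlation). Quantile normalization ended these calls (0.294 at 4 d and 0.0524 at 5 d), and TMM factors that at 4 d (0.225). TMM factors and quantile normalization ended the call at 24 h too (0.251 and 0.234). JAZ10 was lower at 5 d (log2 fold change -1.91 ± 0.34). The jasmonate call at 24 h (camera adjusted p = 0.0192, and adjusted p = 0.713 with an estimated correlation) rested on NPA replicate 1. Without it the median was -0.42 (adjusted p = 0.822). Of 15 ethylene genes, ACS8 was lower from 6 h to 4 d, most at 24 h (log2 fold change -2.38 ± 0.18, adjusted p = 6.17e-07), when the list stood below others (camera adjusted p = 0.0192, and adjusted p = 0.368 with an estimated correlation). This list call was lost without mock replicate 1 (adjusted p = 0.203), at mean TPM of at least 5 (0.185) and at a pseudocount of 0.1 (0.0531). PAD3 was the only one of 17 salicylate and defence genes called at any time, lower at 24 h (log2 fold change -1.66 ± 0.33, adjusted p = 0.0102). This was lost without mock replicate 2 or either NPA library. The list was not called (camera adjusted p = 0.587). No clock gene of 15 passed limma at any time (0 under an unadjusted p of 0.05 at each, fry adjusted p = 0.987 at 6 h). SEOR1 among 6 phloem markers was lower at 4 d (log2 fold change -1.56 ± 0.24) and 5 d (camera adjusted p = 0.916 and 0.352). PDF1 among 4 epidermis markers was lower at 5 d (log2 fold change -2.28 ± 0.65, adjusted p = 0.0205). This was lost without mock replicate 2 or NPA replicate 1. The epidermis list was not called (camera adjusted p = 0.917). None of 7 stomatal genes was called by limma at 5 d (1 under an unadjusted p of 0.05; fry adjusted p = 0.442). The list stood above others at 3 d alone (camera adjusted p = 0.0396, 0.413 with an estimated correlation). The call was lost with TMM factors (0.166) and without replicate 1 of NPA or mock. CUC1 was lower from 3 d, at 0.175 ± 0.0778 against 1.58 ± 0.12 TPM at 5 d (log2 fold change -1.14 ± 0.16, adjusted p = 5.72e-05). With no list call and medians between -0.23 and 0, camera directions were higher for auxin synthesis from 2 d, salicylate, phloem and epidermis from 2 d to 4 d and some other lists at single times.

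With NPA 182 genes were higher and 141 lower at 6 h, 176 and 255 at 12 h, and 87 and 304 at 24 h. The counts were 87 and 676 at 2 d, 124 and 1061 at 3 d, 125 and 1921 at 4 d and 422 and 3118 at 5 d. At least 2-fold changes numbered 145 and 95 at 6 h and 177 and 1390 at 5 d. As deposited the share of higher calls fell from 56.3% at 6 h to 6.11% at 4 d and rose at 5 d. It depended on scaling. At 5 d it was 11.9% as deposited, 44.6% with TMM factors (1543 higher, 1913 lower) and 37.5% with quantile normalization. From 12 h to 4 d it was 40.8%, 22.3%, 11.4%, 10.5% and 6.11% as deposited. With TMM factors it was 50.7%, 41.7%, 18.4%, 26.0% and 26.8%, and 53.5%, 36.0%, 17.5%, 25.3% and 25.6% with quantile normalization. The all-gene median was -0.02 at 6 h, between -0.12 and -0.05 at later times, and above 0 with TMM factors from 12 h on. Leaving out mock 6 h replicate 2 or NPA 6 h replicate 1 lowered the 6 h count from 323 to 192 or 175. At 12 h (431 genes) the count was 167 without NPA replicate 1, 825 without NPA replicate 2, and 231 and 250 without mock replicates 1 and 2. Deviations of mock and NPA libraries of the same replicate number ran opposite at 6 h, 12 h and 24 h (r of -0.57, -0.58 and -0.36 across genes, which are not independent replicates). A replicate block crossed within times, chosen after the data were seen, gave 1253 genes at 12 h and 698 at 24 h. Any left-out library gave 119 to 248 at 24 h (391), 332 to 426 at 2 d (763) and 612 to 655 at 3 d (1185). At 4 d (2046) the count was 1247 without mock replicate 1 and 1334 without NPA replicate 1. At 5 d (3540) it was 1502 without mock replicate 2 and 2165 without NPA replicate 2. With only the 4 libraries of a comparison fitted, limma called 0 genes at 6 h (1534 under an unadjusted p of 0.05), 0 at 12 h (2002), 2 at 24 h (2232), and 0 at 2 d (2855). It called 2738 at 3 d, 3675 at 4 d and 1260 at 5 d. The early single-gene calls rest on the spread pooled over all groups.

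Over the mean of the 7 times, 14 libraries against 14, 1364 genes were higher and 6311 lower with NPA (17.8% higher as deposited, 52.6% with TMM factors and 48.3% with quantile normalization). All 12 called root founder genes were lower, as were 33 of 35 cell cycle, all 11 xylem, all 6 cambium and all 14 ribosome genes. Higher were 10 of 23 jasmonate and 10 of 34 photosynthesis genes. The NPA effect differed between times in 1210 genes. Of 4165 genes called at 1 or more times, 46 were lower at all 7 times and 5 higher at all 7. No chance value is given for these counts, since the calls of a gene at different times share 1 estimate of its spread. The former included LBD16, LAX2, GATA23, IAA20, IAA30, TMO6 and the expansin gene EXPA4, and the latter CYP81D11 and MAKR6. Those outside the fixed rule were singled out after their values were seen. A further 97 genes, ARR4 among them, were higher at 1 or more times and lower at another.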

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

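The tests of a wound response at T0, of clock phase at 6 h and of jasmonate genes beside CYP81D11 were chosen after the results they bear on were seen, and the clock test at 6 h took its present form after 2 versions with clock covariates, which moved folds not at all or little, had been run.

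The T0 libraries stood apart from each other, with 4001 genes more than 2-fold apart (2602 higher and 1399 lower in replicate 2). Of 9 further genes with a known phase, 8 moved as a different time of day would give, such as CAT2 (1813 TPM in replicate 1 and 113 in replicate 2) and CAT3 (99.8 and 1623), while RVE2 moved the other way (30.5 and 115), so different clock phases at harvest are a candidate explanation for part of the difference. Of 172 genes raised in every later library, 72.1% lay below all of them in T0 replicate 2. This argues only against a library of 6 h or later. Whether replicate 2 had begun a wound response stays open: the wound and jasmonate list had been seen higher there before it was tested, so its median of 1.76 on the log2 scale, at percentile 100 of 10000 random lists, decides nothing. Jasmonate genes also follow the time of day, and no biological difference between the T0 samples is given by the labels or was tested.

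Auxin response genes parted at 6 h of NPA, with GH3.3 higher and IAA1, IAA2, IAA5, IAA19, IAA20 and IAA30 lower. Clock phase of the harvest was excluded as the whole cause: the 2 libraries of each treatment lay at different phases (8 of 15 clock genes more than 2-fold apart in both, in opposite directions), yet 0 of the 7 genes differed between them by 50% of its NPA difference. The largest such difference was 0.37 on the log2 scale, and between mock and NPA libraries of like phase the smallest was 1.37. A single library was excluded as the source of the directions, since leaving out each of the 4 libraries gave 0 sign changes among the 7 genes. A local rise of auxin for GH3.3 with less auxin where the IAA genes are expressed may be at work, as could a direct effect of NPA, and neither was tested.

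CYP81D11 was higher with NPA at each of 7 times. A response to NPA as a foreign chemical is a candidate explanation: 8 of 14 other detoxification genes were called higher over the mean of the times, against 1364 of 20654 genes tested (with TMM factors 9 of 14 against 3781 of 20609, with quantile normalization 9 of 14 against 3641 of 20654). Their changes were small, from 0.20 (OPR2) to 1.00 (UGT74E2), and GSTU25 (-0.85) and ABCG40 (-0.28) were lower. Whether the higher jasmonate genes account for it stays open: at 5 of the 7 times no member of the wound and jasmonate list was called higher, but 10 of 23 were over the mean of the times, and a missing call in 2 libraries against 2 excludes nothing.

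The comparison of NPA with mock over the mean of the times was set against 100 splits of the 28 libraries within times, the real one included. The real groups gave 7675 genes, and the highest of the other splits gave 1981. Other splits mix mock and NPA libraries in a group, so the NPA effect adds to their spread and lowers their counts. A difference between cultures or batches would stay with the real groups, and the splits cannot exclude it.

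The effect of NPA differed between times, by limma's F test of the 6 differences, in 1210 genes, and it was looked up gene by gene for 34: the fixed genes and the highest and lowest with NPA. The 19 of these 34 that differed are given here with their adjusted p, without the named list members, of which many differed too, such as MYB36 (1.39e-08), ARR4 (3.56e-07), CYCB2;2 (7.83e-06), PUCHI (1.56e-06), PLT3 (5.18e-06) and JAZ10 (7.56e-06). Of the 19, those of roots and division were WOX11 (2.92e-05), WOX7 (7.05e-05) and CYCB1;1 (0.00124), and those of auxin response GH3.3 (4.33e-08), GH3.2 (0.000644) and IAA19 (0.0111). Genes higher with NPA at 6 h, 12 h or 24 h were Rap2.6L (8.36e-09), TPPD (8.11e-06), GolS1 (0.0239), CYP94B1 (4.32e-06) and NRT2.6 (0.00107), of which Rap2.6L and TPPD were lower at 5 d (log2 fold changes -1.19 and -2.03). Genes lower with NPA at 6 h or from 2 d on were ACL5 (0.00089), AGP31 (0.00202), PR-1-LIKE (1.49e-10), PYK10 (2.57e-05), GRP9 (3.77e-06) and GASA5 (3.03e-06), and NAS2 (1.26e-05) was higher at 4 d and 5 d. PELPK1 (9.74e-09) was higher at 3 d (log2 fold change 2.58) and lower at 5 d (-2.86).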

How the results depend on the processing

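The clock covariates, the crossed replicate block and the calls kept without each T0 library were chosen after the data were seen, and the other alternatives before the data were examined. In mock against T0 and NPA against mock no named gene with a call, in the main fit or in the alternative, turned its direction under any alternative run. Changes of sign in genes with no call in either fit were not counted. In the 12 h to 24 h step of mock, GRP7 (log2 fold change 4.79) and GI (3.75) turned to -0.18 and -0.03 with clock components over all libraries. Without organelle genes, without the 20 highest genes, without the trend and with the replicate block, each count stayed within 1.5 times its value (NPA at 5 d 3428 with the block, against 3540). Where a value moved, the cause was not tested, except that a minimum fold and a stricter filter call or test fewer genes and that fewer libraries give fewer degrees of freedom. Depth is unknown, so its limits cannot be given, and low genes such as WOX5 rest on the pooled spread.

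With a minimum absolute log2 fold change of 1 the counts from 6 h to 5 d were 2413, 2100, 3018, 3069, 3821, 4004 and 4885 in mock against T0, 271, 238, 401, 572, 1071 and 1567 with NPA from 12 h on, 534 and 879 for the 12 h and 24 h steps, 156, 165 and 117 for the 3 d to 5 d steps and 404 for the mean over times. With genes of mean TPM of at least 5 alone the counts with NPA were 137, 203, 167, 297, 395, 746 and 1806, the 2 d to 5 d steps held 34, 61, 61 and 4 and the difference between times 315. The root founder median against T0 turned to -0.62 at 4 d and -0.74 at 5 d there. With no filter the 4 d and 5 d steps held 661 and 555, at a pseudocount of 5 660 and 322, and at a pseudocount of 0.1 226 and 33, with 28 for 2 d. Quantile normalization gave 663 for the 4 d step and turned the photosynthesis median at 12 h against T0 to 0.0248. TMM factors kept 7505 of 11006 calls at 5 d against T0 and 2334 of 3540 with NPA at 5 d, and moved the shares of higher calls given with the counts.

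With only the libraries compared, limma called 113, 220, 439, 291, 1602, 2260 and 2794 genes in mock against T0 from 6 h to 5 d, 0, 0, 2, 0, 2738, 3675 and 1260 with NPA, 0, 0, 0, 1, 3515 and 1 in the steps and 9011 for the mean over times. Under an unadjusted p of 0.05 were 1534, 2002, 2232 and 2855 genes with NPA from 6 h to 2 d, and 3949, 5468, 1396, 3488 and 2993 in the 12 h, 24 h, 2 d, 3 d and 5 d steps. Called both without T0 replicate 1 and without T0 replicate 2 were 3385, 2782, 4352, 4688, 5820, 6190 and 7229 genes.

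With clock components over all libraries as covariates the counts were 7751 for mock at 12 h against T0, 586, 1171, 1399, 1544, 2463, 3682 and 6290 with NPA and 32, 224, 910 and 706 in the 24 h to 4 d steps. The 24 h step lost most calls, from 3048. With components of the within-group deviations, which cannot change a fold (largest shift 0) and take up spread within groups, they were 7947, 594, 1644, 1259, 1573, 2357, 3677 and 6300, and 5874, 7813, 247, 740 and 2138 in the 12 h to 4 d steps. A replicate block crossed within times gave 1253 genes at 12 h and 698 at 24 h of NPA, with numbers crossed at 5 of the 7 times.

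With an estimated correlation camera called 0 lists (50 as preset) in mock against T0 and 1 (64 as preset) with NPA, cambium at 6 h, and fry called 105 and 50. For 13 list results fry passed with a direction opposite to camera's. In mock against T0 these had medians of 0.11 (fry adjusted p = 0.029), 0.20 (0.0439), 0.10 (0.0235), 0.18 (0.0151) and 0.26 (0.029) for auxin transport at 6 h, 24 h, 2 d, 4 d and 5 d. The median was 1.35 (0.0153), 1.20 (0.0129) and 1.55 (0.00265) for the clock at 24 h, 2 d and 3 d, and 0.0399 (0.0119) and -0.22 (0.0415) for auxin response at 4 d and 5 d. It was 0.48 (0.0152) for phloem at 3 d, 0.61 (0.00978) for ethylene at 5 d, and -0.11 (0.0447) for auxin synthesis with NPA at 5 d. None of these had a camera call, and fry asks another question, whether members move on balance, while camera compares them with other genes.

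With each library left out in turn the counts ran, in mock against T0, from 4122 to 9433 at 6 h, 3525 to 7381 at 12 h, 5629 to 11033 at 24 h, 6325 to 11097 at 2 d, 7562 to 12149 at 3 d, 7683 to 12057 at 4 d and 8683 to 12670 at 5 d. With NPA they ran from 175 to 236 at 6 h, 167 to 825 at 12 h, 119 to 248 at 24 h, 332 to 426 at 2 d, 612 to 655 at 3 d, 1247 to 1502 at 4 d and 1502 to 2884 at 5 d. The steps ran from 288 to 1417 for 12 h (lowest without mock 6 h replicate 1), 296 to 1798 for 24 h (without mock 24 h replicate 2), 17 to 50 for 2 d (without mock 24 h replicate 1), 88 to 135 for 3 d (without mock 3 d replicate 1), 138 to 153 for 4 d (without mock 3 d replicate 1) and 75 to 161 for 5 d (without mock 5 d replicate 2). The mean over times ran from 6746 to 7816 and the difference between times from 946 to 1209. The ribosome median with NPA at 6 h ran from -0.43 without mock 6 h replicate 2 to 0.0074 without replicate 1, and the wound and jasmonate median at 24 h from -0.42 without NPA 24 h replicate 1 to 0.67 without replicate 2.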

Other observations

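No test of a hypothesis is reported here, and the genes below were picked after their values were seen, from the 97 that were higher with NPA at 1 or more times and lower at another. Those named first act in the synthesis of suberin, the waxy barrier of root and wound tissue, and are given at 3 d, 4 d and 5 d, but no list of suberin genes was tested. CYP86A1, a fatty acid hydroxylase gene of suberin synthesis, had log2 fold changes of 1.95, -1.72 and -3.20 at these times. GPAT5, an acyltransferase gene, stood at 0.94, -0.76 and -1.83, FAR5, a reductase gene, at 1.12, -0.86 and -2.94, and CYP86B1 at 0.92, -0.93 and -1.91. The exporter gene ABCG6 (1.31, -1.19 and -2.08) and the factor gene MYB107 (0.51, -0.65 and -1.22) ran the same course, as did the laccase genes LAC3 (1.29, -1.89 and -2.77) and LAC5 (1.21, -1.34 and -2.44).

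ARR4, a cytokinin response regulator gene, had log2 fold changes with NPA of 2.46, 1.69 and 1.20 at 6 h, 12 h and 24 h and of -0.99 and -1.30 at 4 d and 5 d. WOL, a cytokinin receptor gene, stood at 1.14 at 6 h and -1.13 at 5 d, and UGT76C2, which glucosylates cytokinin, at 1.04 and -1.76. The pectinase gene QRT2 stood at 2.23 at 6 h and -2.04 at 5 d, and the peptide gene PROPEP4 at 2.58 and -1.52. The auxin repressor genes IAA1 and IAA2 went the other way, from -2.25 and -2.05 at 6 h to 1.66 and 0.95 at 5 d.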
